A study of Homo sapiens with 8 samples.

How the data were processed

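Poly(A)-selected RNA of U2OS cells, an established human osteosarcoma line, was measured by RNA sequencing on an Illumina HiSeq instrument, per the labels' protocols. The cells expressed either an actin mutant, G13R, or GFP as the control, and each was sampled in normal growth and after serum stimulation. The labels thus gave 4 groups with 2 libraries each, 8 libraries in all. They do not say which of the actin genes carries the mutation, how long serum was applied, or whether serum was withdrawn first.

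The authors deposited 1 table with an FPKM value (fragments normalized to transcript length and to mapped fragments) per gene and library. TopHat2 2.0.13 and Cufflinks 2.2.1 are named as the tools, and hg19 and the fly build BDGP5 as the genome builds, per the submitters' processing notes. The table had 22504 genes and 0 fly genes, and the gene annotation used is not given in the sources used here. Its columns were matched to libraries by name, with C read as normal growth, and 0 columns were left unmatched. Gene starts were found to count from 0, because end minus start was a multiple of 3 for 81.8% of 148 olfactory receptor genes spanning under 1000 bases, so 1 was added to each start. All coordinates are therefore 1-based hg19 positions of the whole gene span. A spreadsheet had turned 28 symbols into dates, and those genes were tested but not named.

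FPKM values keep no read counts, so the depth behind each value is unknown and no counting interval was computed. Among genes under 0.25 FPKM, the commonest ratio between a library and G13R normal replicate 2 gave relative depths from 0.717 to 1.2, but only 13.0 to 16.05% of gene pairs lay at that ratio. Reads were therefore not recovered, and no count model was run. Cufflinks divides reads among transcripts, so values of near-identical genes such as HSPA1A with HSPA1B are uncertain, as are those of overlapping or antisense genes.

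Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend and 1 mean per group. Genes with at least 1 FPKM in at least 2 libraries were kept, which left 12996. All 8 libraries shared 1 estimate of the spread per gene, with 4 residual degrees of freedom. Calls had a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The contrasts were serum against normal growth in GFP cells and in G13R cells, G13R against GFP cells in normal growth and after serum, and the difference between the serum responses. Adjusted p-values given for genes come from these limma fits unless stated otherwise.

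Before the data were examined, 23 gene lists with 530 members were fixed from textbook knowledge, and 475 members could be tested. The lists were immediate-early, SRF and MRTF targets, YAP and TEAD targets, growth factor delayed-early, FOXO and starvation, G1/S cell cycle, G2/M cell cycle, cholesterol and SREBP, p53 targets, interferon-stimulated, NF-kappaB and cytokine, unfolded protein and ATF4, heat shock, matrix and adhesion, TGF-beta targets, RNA polymerase II subunits, Pol II pausing and Mediator, actin dynamics and nuclear transport, hypoxia and glycolysis, ribosome biogenesis, oxidative phosphorylation, ribosomal proteins, and replication-dependent histones. Each was tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all 115 tests. Marker sets for osteoblast lineage, epithelial, leukocyte, neural and endothelial cells were fixed at the same time.

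Named genes followed a rule fixed before the data were examined. It took, per contrast, up to 8 called genes each way with the largest log2 fold changes, no overlap between the groups' libraries and a mean of at least 2 FPKM. It added the 3 called members of each list with the largest changes. The 6 actin genes, FOS, EGR1, SRF, VCL, CTGF, CYR61 and MYC were always included, and a contrast with fewer than 5 passing genes gave its 10 genes of smallest p instead. Unnamed transcripts were skipped.

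The overlap of the serum responses was set against independent lists of the same sizes. In a cross-check against selection, genes that moved at least 2-fold in 1 pair of libraries were measured in the pairs not used to choose them. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, only the compared libraries in the fit, limma without the trend, the replicate number as a block, a 2-fold minimum for counts of genes, and leaving out each library in turn. Leaving out genes spanning under 200 bases and leaving libraries out of the list tests were added after seeing the data. So were quantile normalization in the cross-check, the alternatives for called marker genes, and the settings of the overlap other than the pseudocount, the filter at 5 FPKM and leaving out libraries. Counts-based tests and scaling to fly genes had been planned in case the table held counts or fly genes, and were not run. Shared 50-base windows between transcripts were counted with Python 3.11.15 on GENCODE 29 transcript sequences, from which no coordinates were taken. Tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

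The fits were tested on simulated data drawn around each gene's real mean with its fitted spread for all 12996 genes, with 200 genes changed in GFP cells after serum. For the serum response of GFP cells, 40% of genes changed 1.5-fold, 88.8% of those changed 2-fold and 100% of those changed 4-fold were recovered. For G13R against GFP cells after serum the shares were 36.2%, 80% and 97.5%, and for the difference between the responses 11.2%, 52.5% and 90%. False calls numbered 6, 8 and 7 in these contrasts, and 0 in the contrasts without simulated change. In the simulated serum response of GFP cells, 0 of 23 unchanged lists passed an unadjusted p of 0.05 in limma's camera, and a list shifted in that simulation had a limma camera p of 2.12e-21. Genes were drawn independently of each other there, so the simulation could not test the effect of correlation between list members. Every group was given the same spread, so the shares recovered may not hold where groups vary unequally.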

Results

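Transcript levels were measured by poly(A) RNA sequencing in U2OS cells, a human osteosarcoma line, that expressed either the actin mutant G13R or GFP. Each kind of cell was sampled in normal growth and after serum stimulation, with 2 libraries in each of the 4 groups. Between 12065 and 12568 genes reached 1 FPKM per library, and the summed FPKM lay between 496166 and 559496. The 2 libraries of a group correlated across genes with Pearson's r from 0.980 in GFP cells after serum to 0.989 in G13R cells in normal growth, where genes are not independent replicates. The first principal component held 53.9% of the variance and set serum against normal growth. GFP serum replicate 2 lay at 44.7 on it, farther out than GFP serum replicate 1 at 26.0 and the G13R serum libraries at 11.8 and 14.5, and 186 genes differed over 2-fold between the GFP serum libraries against 87 to 102 in the other groups. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Errors beside FPKM are SD with n = 2 libraries, and errors beside log2 fold changes are SE.

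The actin genes were read first, as a check of the labels. ACTB, which encodes cytoplasmic beta-actin (chromosome 7, 5566782 to 5603415), stood at 2690 ± 125 FPKM in GFP cells and 10630 ± 873 in G13R cells in normal growth, and at 2579 ± 50.8 and 8313 ± 514 after serum. It was higher in G13R cells by a log2 fold change of 1.98 ± 0.08 in normal growth (adjusted p = 2.80e-06) and 1.69 ± 0.08 after serum (adjusted p = 1.36e-05). It took the largest share of the FPKM sum in each G13R library, from 1.57 to 2.27%. Quantile normalization, which ties the top rank of each library, gave 1.32 in normal growth with the call kept. ACTG1, the other cytoplasmic actin gene (chromosome 17, 79476997 to 79490873), had 2192 ± 165 FPKM in GFP and 1892 ± 64.9 in G13R cells in normal growth and was not called (log2 fold change -0.21 ± 0.08, adjusted p = 0.257). ACTA2 stood at 4.11 ± 1.43 and 3.66 ± 0.312 FPKM, while ACTA1, ACTC1 and ACTG2 stayed under 1 FPKM in each library. Of the 50-base windows of the ACTG1 transcript, 0.45% occurred in that of ACTB. The FPKM values cannot tell mutant from endogenous transcripts, so the ACTB excess is not read as regulation of the endogenous gene.

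The serum response of GFP cells, which lack the mutant, is the difference between their serum and normal growth groups. FOS, a component of AP-1 (chromosome 14, 75745477 to 75748933), rose from 4.33 ± 0.407 to 176 ± 94.1 FPKM (log2 fold change 4.95 ± 0.30, adjusted p = 2.25e-05). EGR1, a zinc finger factor (chromosome 5, 137801179 to 137805004), rose from 19.1 ± 1.2 to 232 ± 56.8 FPKM (3.51 ± 0.16, adjusted p = 7.21e-06). CTGF and CYR61, secreted matricellular proteins whose genes respond to SRF and YAP, rose from 189 ± 12.9 to 520 ± 38.2 FPKM (1.45 ± 0.09) and from 156 ± 8.64 to 535 ± 90.6 FPKM (1.76 ± 0.11). The matrix metalloproteinase gene MMP3 (chromosome 11, 102706532 to 102714534) fell from 153 ± 30.4 to 24.03 ± 9.20 FPKM (-2.66 ± 0.21, adjusted p = 4.62e-05). POLR2A, which encodes the largest subunit of RNA polymerase II (chromosome 17, 7387685 to 7417933), fell from 501 ± 6.87 to 287 ± 13.1 FPKM (-0.81 ± 0.07, adjusted p = 8.39e-05). The SRF gene itself had 25.7 ± 0.383 and 21.8 ± 2.13 FPKM and MYC 104 ± 7.83 and 83.8 ± 16.8, with adjusted p of 0.14 and 0.0718.

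Among the immediate-early genes, 19 of 29 rose and 1 fell in GFP cells (19 and 2 adjusted over the list alone; median log2 fold change 1.68), with camera's adjusted p = 9.66e-10 and adjusted p = 0.406 with an estimated correlation. Sterol synthesis genes under SREBP control rose in 24 of 25 cases and in 24 adjusted over the list alone (median 1.30, adjusted p = 1.94e-18, and adjusted p = 0.405 with an estimated correlation). Examples were INSIG1, which retains SREBP in the endoplasmic reticulum (2.85 ± 0.19), the fatty acid desaturase gene FADS2 (2.52 ± 0.20) and the sterol oxidase gene MSMO1 (1.90 ± 0.13). Of the FOXO and starvation genes, which growth factors usually repress, 12 of 18 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 8.88e-06, and adjusted p = 0.406 with an estimated correlation). Among them was the ubiquitin ligase gene FBXO32 (2.16 ± 0.13). The p53 targets had 15 of 22 higher and 2 lower (16 and 3 adjusted over the list alone; adjusted p = 1.38e-04, and adjusted p = 0.435 with an estimated correlation). The interferon-stimulated genes had 12 of 17 higher (14 adjusted over the list alone; adjusted p = 2.19e-05, and adjusted p = 0.405 with an estimated correlation), with STAT2 at 1.33 ± 0.16.

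Ribosome biogenesis genes moved the other way, with all 22 tested members lower in GFP cells after serum, over all genes and adjusted over the list alone (median -0.95, adjusted p = 1.78e-14, and adjusted p = 0.406 with an estimated correlation). RRP9, a component of the box C/D snoRNP that processes ribosomal RNA, fell from 75.4 ± 4.57 to 27.3 ± 8.69 FPKM (-1.47 ± 0.17), with RRS1 at -1.43 ± 0.17. Heat shock genes fell in 10 of 14 cases, also 10 adjusted over the list alone (median -0.53, adjusted p = 1.93e-05, and adjusted p = 0.406 with an estimated correlation), including the mitochondrial chaperonin genes HSPD1 (-1.02 ± 0.10) and HSPE1 (-0.91 ± 0.08). Of 12 RNA polymerase II subunit genes 7 fell (8 adjusted over the list alone; adjusted p = 8.42e-04, and adjusted p = 0.406 with an estimated correlation). The G1/S genes had 7 of 22 lower (7 adjusted over the list alone; adjusted p = 0.0415, and adjusted p = 0.520 with an estimated correlation), with CDC45, a replication helicase factor, at -0.63 ± 0.11. This list's adjusted p was 0.344 under quantile normalization, 0.124 without GFP normal replicate 2, 0.0759 without GFP serum replicate 1 and 0.0514 without GFP serum replicate 2. The SRF and MRTF targets, with 7 higher and 4 lower of 29 (9 and 6 adjusted over the list alone), did not pass (adjusted p = 0.180). Neither did the YAP and TEAD targets, with 9 higher and 3 lower of 20 (9 and 3 adjusted over the list alone; adjusted p = 0.0522). Under quantile normalization both lists passed, each with adjusted p = 0.0153.

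In all, 1941 genes rose and 2044 fell in GFP cells after serum, 30.7% of the 12996 tested, and 523 and 165 of them did so at least 2-fold. The total of 3985 was 2155 without GFP normal replicate 1, 2527 without GFP normal replicate 2 and 2494 without GFP serum replicate 2.

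**Figure D1:**
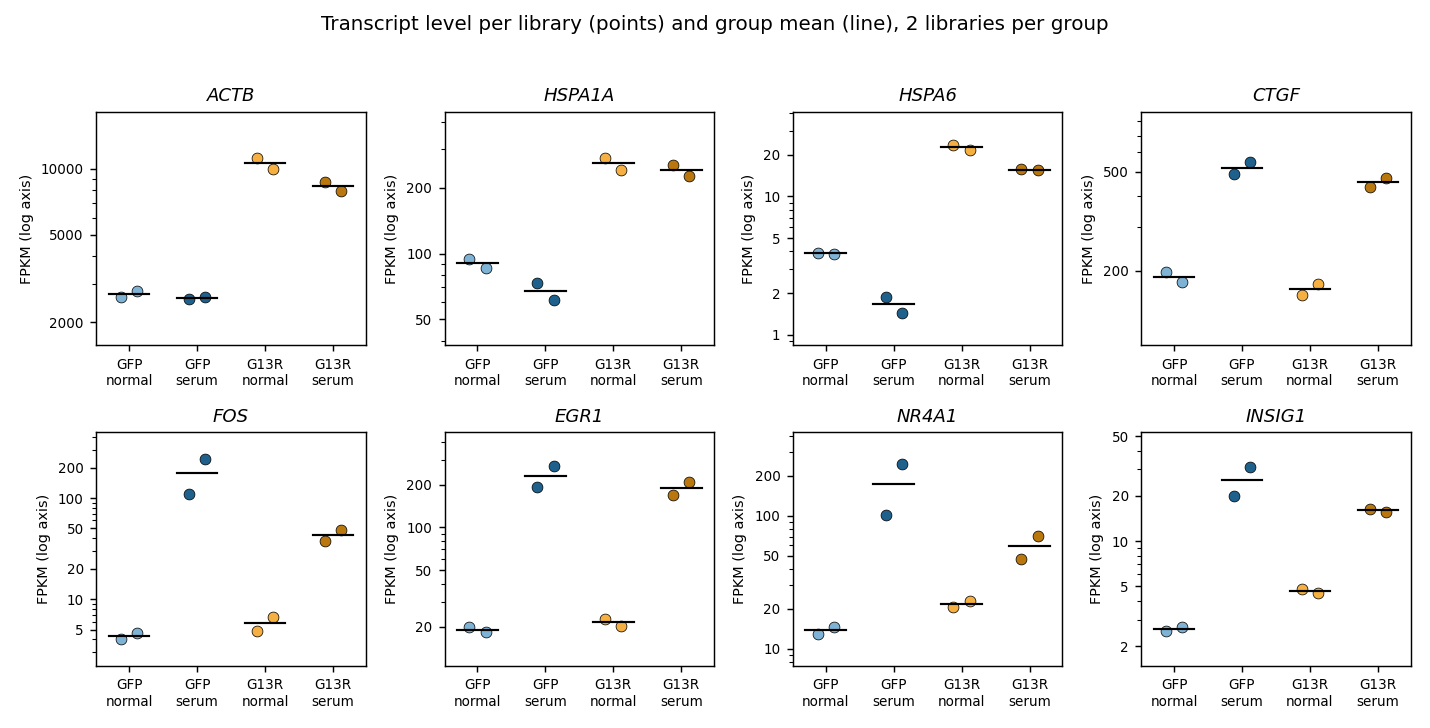
FPKM of ACTB, HSPA1A, HSPA6, CTGF, FOS, EGR1, NR4A1 and INSIG1 in each of the 8 libraries (points, log axis), with the mean of each group's 2 libraries as a line. ACTB lay between 7949 and 11240 FPKM in the G13R libraries and between 2543 and 2779 in the GFP libraries, while FOS reached 176 FPKM on average in GFP cells after serum and 43.2 in G13R cells.

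The serum response of G13R cells is likewise the difference between their serum and normal growth groups. EGR1 rose from 21.5 ± 1.82 to 190 ± 27.6 FPKM (log2 fold change 3.08 ± 0.16, adjusted p = 3.45e-05) and FOS from 5.77 ± 1.32 to 43.2 ± 7.75 FPKM (2.71 ± 0.30, adjusted p = 7.36e-04). CTGF rose by 1.43 ± 0.09 and CYR61 by 1.71 ± 0.11. TNFRSF11B, which encodes the decoy receptor osteoprotegerin (chromosome 8, 119935796 to 119964439), rose from 6.42 ± 1.51 to 61.9 ± 14.0 FPKM (3.08 ± 0.21, adjusted p = 4.44e-05). MMP3 fell from 291 ± 20 to 54.6 ± 1.36 FPKM (-2.39 ± 0.21, adjusted p = 2.04e-04). TGFBI, a TGF-beta-induced matrix protein gene (chromosome 5, 135364584 to 135399507), fell from 49.8 ± 0.583 to 15.6 ± 2.19 FPKM (-1.62 ± 0.13, adjusted p = 1.09e-04).

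Of the 29 immediate-early genes, 14 rose in G13R cells and none fell (21 adjusted over the list alone; median 0.94, adjusted p = 1.43e-09, and adjusted p = 0.406 with an estimated correlation). The Kruppel-like factor gene KLF6 rose by 1.77 ± 0.14. Sterol synthesis genes rose in 24 of 25 cases and in 24 adjusted over the list alone (median 0.89, adjusted p = 9.56e-20, and adjusted p = 0.405 with an estimated correlation), with FADS2 at 2.08 ± 0.20 and INSIG1 at 1.59 ± 0.19. The interferon-stimulated genes had 7 of 17 higher (9 adjusted over the list alone; adjusted p = 8.14e-05, and adjusted p = 0.405 with an estimated correlation), with the RNA sensor gene DDX58 at 1.15 ± 0.15. Of the FOXO and starvation genes 6 of 18 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.5 with an estimated correlation). Of the p53 targets 5 of 22 rose (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.00344, and adjusted p = 0.489 with an estimated correlation). SRF and MRTF targets passed here, with 7 of 29 higher and 2 lower (10 and 2 adjusted over the list alone; adjusted p = 0.0337, and adjusted p = 0.5 with an estimated correlation). Those higher included the focal adhesion genes TGFB1I1 (1.76 ± 0.22) and VCL (0.71 ± 0.11). Among the 2 lower was ACTB (-0.35 ± 0.08, limma adjusted p = 0.0184), whose value may include mutant transcripts. This ACTB call was lost in 6 of the settings tried. YAP and TEAD targets had 6 of 20 higher (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.0415, and adjusted p = 0.406 with an estimated correlation). The SRF and YAP medians were 0.114 and 0.117 in G13R cells, against 0.181 and 0.427 in GFP cells. Neither list passed camera's test of the difference between the responses (adjusted p = 0.609 and 0.307), so no difference between the cells is read from these passes. The SRF list's adjusted p was 0.129 without G13R serum replicate 1, and the YAP list's was 0.0681 without G13R normal replicate 1.

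Ribosome biogenesis genes fell in 10 of 22 cases in G13R cells (19 adjusted over the list alone; median -0.49, adjusted p = 3.79e-11, and adjusted p = 0.406 with an estimated correlation). Heat shock genes fell in 6 of 14 cases (7 lower and 1 higher adjusted over the list alone; adjusted p = 2.14e-04, and adjusted p = 0.406 with an estimated correlation), with HSPD1 at -0.67 ± 0.10. Of 14 TGF-beta targets 7 fell and 2 rose (8 and 3 adjusted over the list alone; median -0.61, adjusted p = 0.00284, and adjusted p = 0.448 with an estimated correlation). ID3, an inhibitor of basic helix-loop-helix factors, fell from 128 ± 1.92 to 36.5 ± 3.16 FPKM (-1.79 ± 0.29). The median of this list was -0.40 without G13R serum replicate 2. RNA polymerase II subunit genes fell in 4 of 12 cases (4 adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.406 with an estimated correlation; 0.0606 under quantile normalization), with POLR2A at -0.50 ± 0.07. The Pol II pausing and Mediator list had 1 of 22 lower, ELL2 (1 adjusted over the list alone; adjusted p = 0.0147, and adjusted p = 0.406 with an estimated correlation). The G2/M list had 2 of 22 lower, AURKA and PLK1 (1 adjusted over the list alone; adjusted p = 0.00904, and adjusted p = 0.576 with an estimated correlation). The calls of ELL2, AURKA and PLK1 were lost in 4, 4 and 8 of the settings tried, with adjusted p up to 0.1, 0.0991 and 0.235. In all, 1074 genes rose and 601 fell in G13R cells after serum, 241 and 54 of them at least 2-fold. The total of 1675 was 932 without the filter on low values, 1071 without the intensity trend, 492 and 655 without G13R normal replicates 1 and 2, and 487 and 413 without G13R serum replicates 1 and 2.

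Whether the 2 serum responses involved the same genes was tested on their overlap, and these responses share no library. Of the 1675 genes called in G13R cells, 1312 were also called in the same direction in GFP cells, 822 higher and 490 lower, where independent lists would share 160 and 94.5. In 3 genes the calls had opposite directions. Across all tested genes the log2 fold changes correlated with Pearson's r = 0.687 and Spearman's rho = 0.694, and 76.8% had the same sign. The shared count was 720 without the filter on low values, 846 without the trend, 449 and 540 without G13R normal replicates 1 and 2, 439 and 356 without G13R serum replicates 1 and 2, and 853 without GFP normal replicate 1.

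**Figure D2:**
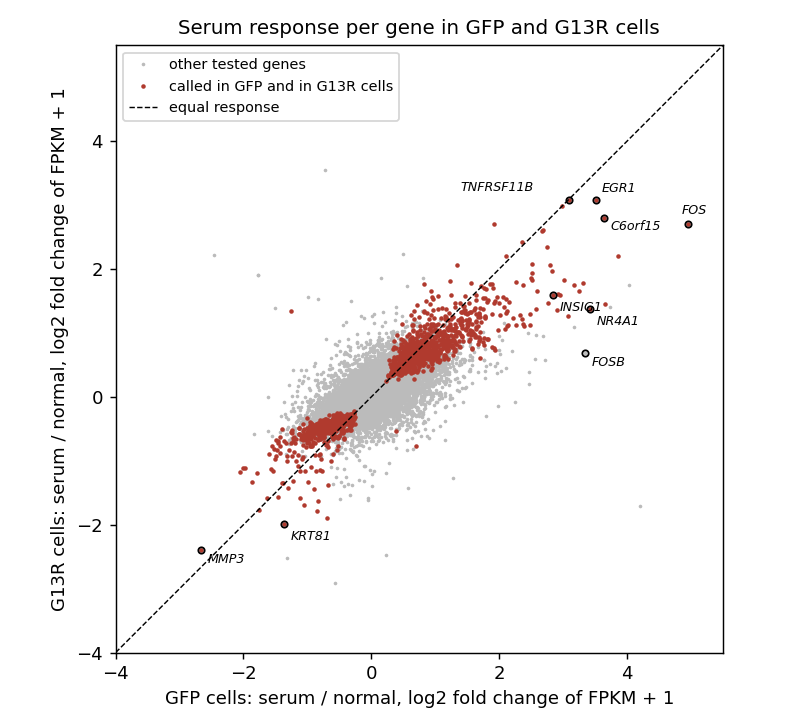
Log2 fold change after serum for each tested gene in GFP cells (horizontal axis) and in G13R cells (vertical axis), with genes called in both in red. The 1312 genes called in the same direction lie in the upper right and lower left, and FOS lies at 4.95 in GFP cells and 2.71 in G13R cells.

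G13R cells were compared with GFP cells in normal growth to show how the cells differed without serum stimulation. Of the 5 called genes beside ACTB, 3 were stress-inducible HSP70 genes. HSPA6 (chromosome 1, 161494036 to 161496681) stood at 3.87 ± 0.0436 FPKM in GFP and 22.7 ± 1.49 in G13R cells (log2 fold change 2.28 ± 0.15, adjusted p = 1.62e-04). HSPA1A (chromosome 6, 31783291 to 31785723) stood at 90.2 ± 6.12 and 258 ± 22.9 FPKM (1.51 ± 0.11, adjusted p = 2.20e-04), and its neighbour HSPA1B (31795512 to 31798031) at 76.5 ± 3.77 and 227 ± 20.9 FPKM (1.55 ± 0.11, adjusted p = 2.20e-04). HSPA1A and HSPA1B share 71.4% of their 50-base windows and cannot be read as separate measurements. PMEPA1, a TGF-beta target, was higher (0.97 ± 0.12) and DBNDD2 lower (-0.78 ± 0.10), both with adjusted p = 0.0268, and these calls were lost in 8 and 7 of the settings tried. FOS (0.34 ± 0.30) and EGR1 (0.16 ± 0.16) did not pass in normal growth.

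Of 14 TGF-beta targets, 1 was called higher in G13R cells in normal growth and 13 were not called (6 higher adjusted over the list alone). The list was higher as a whole (median 0.66, adjusted p = 9.58e-12, and adjusted p = 0.405 with an estimated correlation). The G2/M and G1/S lists were lower without a single called member. Adjusted over the list alone, 16 and 11 of their 22 members each were lower (medians -0.33 and -0.30, adjusted p = 7.50e-09 and 1.69e-07, each with adjusted p = 0.406 with an estimated correlation), and the medians were -0.175 and -0.179 under quantile normalization. Ribosomal protein genes were lower (0 of 26 called, 13 adjusted over the list alone, median -0.22, adjusted p = 2.08e-09, and adjusted p = 0.477 with an estimated correlation), but quantile normalization gave -0.01 and adjusted p = 0.626. The heat shock list was higher by the test (adjusted p = 0.00861, and adjusted p = 0.489 with an estimated correlation), with 2 of 14 called and 4 adjusted over the list alone, while its median was -0.08 (0.09 under quantile normalization) and its mean 0.21. The 2 called were HSPA1A and HSPA1B, which are not separate measurements. The other 12 members had a median of -0.125, with 4 above 0. All tested genes had a median of -0.074 in this contrast, and camera's direction is relative to the other genes. The SRF and MRTF targets were lower by the test (adjusted p = 0.0257, and adjusted p = 0.489 with an estimated correlation; median -0.16, mean 0.02), but the median was -0.013 under quantile normalization and -0.078 under median-ratio scaling. Its 1 called member of 29, ACTB, whose value may include mutant transcripts, went in the other direction, and 1 was higher and 8 lower adjusted over the list alone. That list's adjusted p was 0.597 under quantile normalization and 0.0936 without GFP normal replicate 2.

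The immediate-early list was slightly higher in G13R cells in normal growth with 0 of 29 called, also adjusted over the list alone (median 0.15, adjusted p = 8.43e-04, and adjusted p = 0.489 with an estimated correlation). In limma's test, 6 genes differed between G13R and GFP cells in normal growth, 5 higher and 1 lower, with 1968 at an unadjusted p under 0.05. The count was 98 and 109 without GFP serum replicates 1 and 2, which enter only through the shared spread, 14 with a filter at 5 FPKM or with only the compared libraries, 12 under quantile normalization and 11 without genes under 200 bases. With the replicate number as a block it was 83, 13 higher and 70 lower, with all 6 among them.

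After serum, the comparison of G13R with GFP cells asks how the stimulated states differ. The HSP70 genes and ACTB were again higher in G13R cells. HSPA6 stood at 15.6 ± 0.205 against 1.66 ± 0.306 FPKM (log2 fold change 2.65 ± 0.15, adjusted p = 3.55e-05) and HSPA1A at 241 ± 19.7 against 67.4 ± 8.11 FPKM (1.83 ± 0.11, adjusted p = 3.55e-05). FOS was lower in G13R cells (-1.91 ± 0.30, adjusted p = 0.0376), as was ATF3, a stress-responsive factor (-1.39 ± 0.26, adjusted p = 0.0487). The chemokine gene CCL2 stood at 5.76 ± 0.663 FPKM in G13R and 23.8 ± 12.5 in GFP cells (-1.78 ± 0.31, adjusted p = 0.0443). MMP3 was higher in G13R cells (1.2 ± 0.21, adjusted p = 0.0443). The calls of FOS, CCL2 and MMP3 were lost in 10 of the settings tried and that of ATF3 in 11, among them leaving out any single library other than GFP serum replicate 1, with adjusted p up to 0.349 and 0.361. EGR1 (-0.27 ± 0.16, adjusted p = 0.365), CTGF (-0.19 ± 0.09, adjusted p = 0.258) and MYC (0.46 ± 0.12, adjusted p = 0.0910) did not pass.

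Sterol synthesis genes were lower in G13R cells after serum, with 3 of 25 called (20 adjusted over the list alone; median -0.43, adjusted p = 1.43e-09, and adjusted p = 0.406 with an estimated correlation). Heat shock genes were higher, with 2 of 14 called (8 adjusted over the list alone; median 0.27, adjusted p = 1.36e-09, and adjusted p = 0.405 with an estimated correlation). Those called were again HSPA1A and HSPA1B, and the other 12 members had a median of 0.243, with 11 above 0. Ribosome biogenesis genes were higher with 0 of 22 called (10 higher and 1 lower adjusted over the list alone; median 0.33, adjusted p = 4.07e-07, and adjusted p = 0.446 with an estimated correlation). The immediate-early list was lower, with FOS and ATF3 called among 29 (15 lower and 2 higher adjusted over the list alone; median -0.44, adjusted p = 0.00325, and adjusted p = 0.519 with an estimated correlation). The FOXO and starvation list was lower with 0 of 18 called (5 adjusted over the list alone; median -0.43, adjusted p = 4.97e-04, and adjusted p = 0.446 with an estimated correlation). So were the p53 targets with 0 of 22 called (10 lower and 1 higher adjusted over the list alone; median -0.35, adjusted p = 5.63e-04, and adjusted p = 0.446 with an estimated correlation). The G2/M list was lower with 0 of 22 called (12 adjusted over the list alone; median -0.32, adjusted p = 4.07e-07, and adjusted p = 0.439 with an estimated correlation). The delayed-early list was higher with VGF alone called among 21 (8 higher and 1 lower adjusted over the list alone; adjusted p = 2.89e-04, and adjusted p = 0.405 with an estimated correlation). Without GFP serum replicate 2 the medians were 0.13 for ribosome biogenesis, -0.22 for the immediate-early, -0.25 for the FOXO, -0.19 for the p53 and -0.18 for the G2/M list. Without GFP serum replicate 1 they were 0.53, -0.67, -0.61, -0.48 and -0.43 in the same order, with the delayed-early list at 0.30 (0.27 without G13R serum replicate 2) against 0.17 with all libraries. The call of VGF was lost in 8 of the settings tried.

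Between G13R and GFP cells after serum, 107 genes were called, 43 higher and 64 lower, and 51.7% of calls were higher under quantile normalization against 40.2% as deposited. Of 25 calls among named genes, those of ACTB, HSPA1A, HSPA1B and HSPA6 held in every setting run on them, and these 4 genes were also the ones called in both conditions, where independent lists would share 0.0165. The count was 1620 without GFP serum replicate 1 but 9 without GFP serum replicate 2, 6 and 5 without G13R serum replicates 1 and 2, 12 without either G13R normal library and 10 without either GFP normal library. It was 4 without the filter on low values, 6 without the trend or with only the compared libraries, 263 with a filter at 5 FPKM and 180 under quantile normalization. With the replicate number as a block it was 403, 127 higher and 276 lower, with all 107 among them.

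The difference between the serum responses tests directly whether the change from normal growth to serum differed between G13R and GFP cells. Any withdrawal of serum before it was added would be part of that change. FOS had a response lower by -2.24 ± 0.42 on the log2 scale in G13R cells and the related FOSB by -2.66 ± 0.46, but neither passed, each with adjusted p = 0.259. SOCS3, a feedback inhibitor of cytokine signalling, went from 2.67 ± 0.448 to 13.9 ± 5.11 FPKM in GFP cells and from 4.80 ± 0.839 to 4.23 ± 0.369 in G13R cells (difference -2.13 ± 0.33, adjusted p = 0.259). PTX3, a secreted pentraxin gene, went from 24.8 ± 1.5 to 7.54 ± 2.25 FPKM in GFP cells and stood at 12.7 ± 2.09 and 12.6 ± 1.5 in G13R cells (1.62 ± 0.27, adjusted p = 0.259). The responses of CTGF and CYR61 differed by -0.03 ± 0.13 and -0.05 ± 0.16. The limma test called 0 genes, with 1533 at an unadjusted p under 0.05, and the median SE of 0.222 was larger than the 0.157 of the other contrasts.

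The lists were compared in the same way. The immediate-early response was smaller in G13R cells (median difference -0.63, 0 of 29 called, 12 lower and 2 higher adjusted over the list alone, adjusted p = 5.11e-07, and adjusted p = 0.406 with an estimated correlation). The rise of sterol synthesis genes was smaller too (-0.30, 0 of 25 called, 2 lower adjusted over the list alone, adjusted p = 1.99e-07, and adjusted p = 0.406 with an estimated correlation). The fall of ribosome biogenesis genes was smaller, with each of the 22 differences above 0 (0.52, 0 called, 15 adjusted over the list alone, adjusted p = 3.79e-11, and adjusted p = 0.406 with an estimated correlation). The TGF-beta targets had the largest shift among the lists (-0.84, 0 of 14 called, 10 lower adjusted over the list alone, adjusted p = 3.43e-11, and adjusted p = 0.405 with an estimated correlation). This was not a smaller response. The TGF-beta list did not pass in GFP cells (median -0.014, camera's adjusted p = 0.307) and fell in G13R cells (median -0.605). In normal growth it had been higher in G13R than in GFP cells (median 0.656), and the same G13R normal libraries enter both values. Without GFP serum replicate 2 the medians were -0.19 for the immediate-early, -0.18 for the sterol and 0.32 for the ribosome biogenesis list. The count of called genes was 486 without GFP serum replicate 1, 0 without GFP serum replicate 2, 1 without either G13R normal library, 2 and 1 without G13R serum replicates 1 and 2, 1 with a pseudocount of 0.1 and 2 under quantile normalization.

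**Figure D3:**
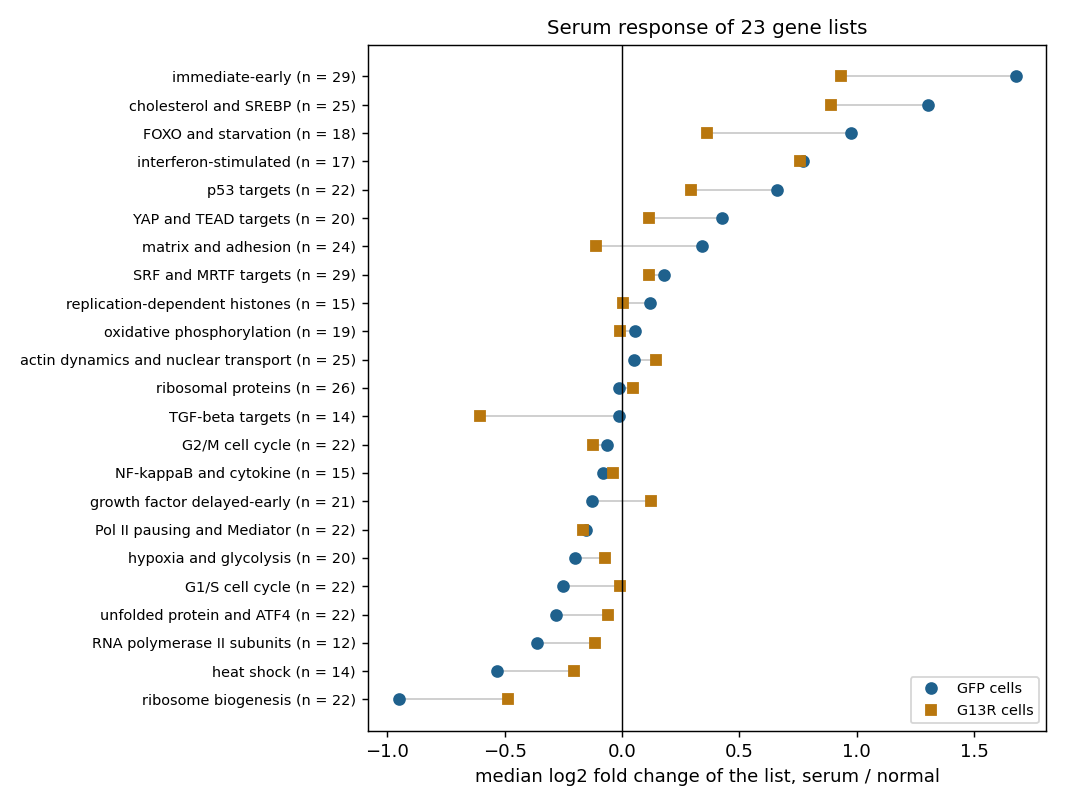
Median log2 fold change after serum of each of the 23 gene lists, in GFP cells (circles) and in G13R cells (squares). The immediate-early list lies at 1.68 and 0.94, the sterol list at 1.30 and 0.89, and the ribosome biogenesis list at -0.95 and -0.49.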

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

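Leaving libraries out of the list tests and quantile normalization in the test of selection were chosen only after the result was seen, while the tests of selection and of scaling were set beforehand. Under the test of the difference between the responses, 10 gene lists responded to serum differently in G13R and GFP cells at camera's preset correlation, and 0 of 23 passed with an estimated one. In log2 units, as G13R minus GFP, the median differences were -0.63 for the immediate-early, -0.49 for the FOXO and starvation, -0.30 for the sterol, -0.30 for the p53, -0.17 for the matrix and -0.84 for the TGF-beta list. They were 0.32 for the delayed-early, 0.31 for the heat shock, 0.21 for the RNA polymerase II subunit and 0.52 for the ribosome biogenesis list. Without GFP serum replicate 2 they were -0.19 for the immediate-early, -0.19 for the FOXO, -0.18 for the sterol and -0.14 for the p53 list, and 0.21 for the delayed-early, 0.17 for the heat shock and 0.32 for the ribosome biogenesis list. The RNA polymerase II subunit median was 0.10 without G13R normal replicate 1 and 0.11 without GFP normal replicate 2, and quantile normalization gave 0.11 for it and -0.26 for the matrix list. Camera's adjusted p lay between 3.43e-11 and 0.0257 at the preset correlation and between 0.405 and 0.446 with an estimated one. The RNA polymerase II subunit list lost its call without GFP serum replicate 1 (adjusted p = 0.0906), without G13R normal replicate 1 (0.148), without GFP normal replicate 2 (0.155) and under quantile normalization (0.179), and the other lists kept theirs in each of these settings. Without GFP serum replicate 2 all 10 lists passed at the preset correlation, with adjusted p from 2.05e-11 to 0.0155.

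The results for lists not described in the report were as follows. For FOXO and starvation genes adjusted p = 4.07e-07 (6 of 18 lower adjusted over the list alone; adjusted p = 0.406 with an estimated correlation). For p53 targets adjusted p = 5.00e-04 (0 of 22 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). For heat shock genes adjusted p = 3.45e-04 (2 of 14 higher adjusted over the list alone; adjusted p = 0.406 with an estimated correlation). For delayed-early genes adjusted p = 0.00904 (6 of 21 higher and 1 lower adjusted over the list alone; adjusted p = 0.405 with an estimated correlation). Matrix genes had adjusted p = 0.00316 (1 of 24 lower adjusted over the list alone; adjusted p = 0.406 with an estimated correlation).

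Most of these lists had a smaller serum response in G13R cells, while the values argued against library scaling as the whole cause, since the immediate-early median was -0.63 as deposited and -0.63 after quantile normalization. GFP serum replicate 2 may carry part of its size, because without that library the immediate-early median was -0.19, still past the threshold at the preset correlation (adjusted p = 4.45e-07), and without GFP serum replicate 1 it was -0.87, and these libraries do not decide which is the better measure. Selection could also shrink a response, and genes chosen in GFP cells responded in G13R cells at 0.624 to 0.743 of their held-out GFP response, while genes chosen in G13R cells responded in GFP cells at 0.995 to 1.203 of their held-out G13R response. That range was 1.131 to 1.283 with a pseudocount of 0.1, 1.027 to 1.234 with a filter at 5 FPKM, 1.082 to 1.386 for genes chosen at 1.5-fold and 0.846 to 1.159 under quantile normalization. These settings do not decide on selection in gene-by-gene comparisons. The members of the lists were fixed before the data were examined, so they were not chosen by their response. The 10 lists flagged were those of 23 that passed on these same libraries, so the sizes of their differences may still reflect selection. An effect of the mutant, which the design names, stays open beside these explanations and was not tested apart from them. The samples hold no cells with added unmutated actin, so an effect of the mutation cannot be told apart from one of added actin. Any serum withdrawal before stimulation would be part of both responses and cannot be told apart either.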

How the results depend on the processing

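Leaving out small genes, leaving libraries out of the list tests and, for the overlap, settings beside the pseudocount, the 5 FPKM filter and leaving out libraries were chosen after seeing the data. The ACTB excess in G13R cells kept its call in every setting run on it, from 1.32 to 2.07 in normal growth and 1.42 to 1.75 after serum. Over 219 results for named genes, 412 alternative values lost and 26 gained a call. Among results called as reported, 0 reversed in sign. The other 3252 values were counted as the same. For results not called as reported, that count also takes any value of opposite sign. The 2-fold minimum was applied to counts of genes only and not run on named genes. Calls held in every other setting for 64 of 78 named genes in the serum response of GFP cells, 38 of 66 in that of G13R cells, 4 of 6 between cells in normal growth and 4 of 25 after serum. Leaving out 1 library gave 2155 to 4263 called genes for serum in GFP cells, 413 to 2366 in G13R cells, 4 to 109 for G13R against GFP cells in normal growth, 5 to 1620 after serum and 0 to 486 for the difference of responses. A lone library was then assumed to vary like the other groups, and fewer libraries lower the power. The fold changes of G13R against GFP cells in normal growth do not use the GFP serum libraries. Increases there without a GFP serum library can therefore come only through the shared spread or the set of genes kept. The GFP serum pair was the most variable, with an SD of 0.367 log2 units between its libraries against 0.289 to 0.323. The cause of the other increases was not tested. The shared serum calls ranged from 356 to 1692, their Pearson's r from 0.619 to 0.677, and the lists past the threshold from 9 to 10, 12 to 13, 11 to 14, 12 to 13 and 9 to 12 in the order of the contrasts.

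A 2-fold minimum left 688, 295 and 47 genes for serum in GFP cells, serum in G13R cells and G13R against GFP cells after serum, by construction. Without the filter the counts were 932 for serum in G13R cells, 4 for G13R against GFP cells after serum and 720 shared, with r = 0.616. Without the trend they were 1071, 6 and 846. A filter at 5 FPKM gave 14 and 263 for G13R against GFP cells in normal growth and after serum, quantile normalization 12 and 180, and only the compared libraries 14 and 6, while leaving out small genes gave 11 in normal growth. For the difference of responses, a pseudocount of 0.1 called 1 gene and quantile normalization 2. The pseudocount of 0.1 also gave r = 0.612 and a cross-check ratio of 1.199 for genes chosen in G13R cells, against 1.07 as reported, and choosing at 1.5-fold gave 1.21. For these the cause was not tested. With an estimated correlation 0 lists passed in any contrast, against 9, 13, 13, 12 and 10 at the preset one, and 2 lists per contrast had an unadjusted p under 0.05. Even the ribosome biogenesis list, with 22 of 22 members lower in GFP cells after serum, had an unadjusted camera p of 0.0651 there. That variant rests on 4 residual degrees of freedom and its power was not simulated, so its failures do not decide against a list.

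The replicate numbers were not taken to pair the libraries, since same-numbered deviations correlated weakly, at 0.017 to 0.121. All these correlations were positive, so a small effect shared by replicate number is not excluded. With the replicate number as a block, limma called 4109, 1797, 83, 403 and 0 genes in the order of the contrasts, 1408 shared serum calls, and 9, 13, 12, 12 and 10 lists. The depth in reads is unknown. By simulation the test of the difference recovered 52.5% of genes that differed 2-fold, with the same spread in every group. The real GFP serum libraries differed more from each other (SD 0.367 log2 units) than the libraries of the other groups (0.289 to 0.323). That share may therefore not hold for these data.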

Other observations

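The heat shock comparison, the HSPA6 read-sharing test, the alternatives for marker genes and the serum-withdrawal test described here were chosen only after the results were seen, while the scaling test was set beforehand. In normal growth several housekeeping lists were lower in G13R cells without a called member. Oxidative phosphorylation genes had a median of -0.21 (6 of 19 lower adjusted over the list alone; adjusted p = 4.13e-05, and adjusted p = 0.406 with an estimated correlation), with a median of -0.04 under quantile normalization. Ribosome biogenesis genes had a median of -0.20 (2 of 22 adjusted over the list alone; adjusted p = 0.00262, and adjusted p = 0.557 with an estimated correlation; median -0.07 under quantile normalization) and hypoxia and glycolysis genes a median of -0.22 (8 of 20 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.446 with an estimated correlation; 0.0747 without GFP normal replicate 2). The hypoxia median was -0.06 under quantile normalization and -0.14 without G13R normal replicate 1. NF-kappaB and cytokine genes were higher (0.29, 5 of 15 higher and 1 lower adjusted over the list alone; adjusted p = 7.78e-04, and adjusted p = 0.405 with an estimated correlation), but the median was -0.045 with the filter at 5 FPKM, 0.15 without G13R normal replicate 1 and 0.17 without GFP normal replicate 2. FOXO and starvation genes were higher (0.16, 0 of 18 adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.489 with an estimated correlation; 0.0525 under quantile normalization), with a median of 0.10 without GFP normal replicate 2. Matrix genes passed upward against a median of -0.04 (mean 0.09, 5 of 24 higher and 2 lower adjusted over the list alone; adjusted p = 0.0298, and adjusted p = 0.406 with an estimated correlation; 0.0515 without G13R normal replicate 1 and 0.0865 without GFP normal replicate 1). Their median was 0.09 under quantile normalization, 0.04 under median-ratio scaling, -0.005 without G13R normal replicate 1, and 0.006 and 0.013 without GFP normal replicates 1 and 2. Camera's direction is relative to the other genes, and the median over all tested genes was -0.074 in this contrast. With the replicate number as a block, the matrix list did not pass camera's test (adjusted p = 0.055).

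After serum, oxidative phosphorylation genes were lower in G13R than in GFP cells (median -0.22, 3 of 19 adjusted over the list alone; adjusted p = 1.52e-04, and adjusted p = 0.406 with an estimated correlation; -0.14 without GFP serum replicate 2). Ribosomal protein genes were lower too (-0.17, 2 of 26 adjusted over the list alone; adjusted p = 1.42e-05, and adjusted p = 0.524 with an estimated correlation), but not under quantile normalization (-0.02, adjusted p = 0.766), and their median was -0.08 and -0.27 without GFP serum replicates 2 and 1. NF-kappaB and cytokine genes were higher while their called member CCL2 was lower (0.23, 6 of 15 higher and 1 lower adjusted over the list alone; adjusted p = 0.00972, and adjusted p = 0.406 with an estimated correlation; 0.12 and 0.38 without GFP serum replicates 2 and 1, and 0.37 without G13R serum replicate 2). The G1/S list was lower with the thymidylate synthase gene TYMS called (-0.14, 4 of 22 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.491 with an estimated correlation; 0.0801 without G13R serum replicate 1 and 0.135 without GFP serum replicate 1), and the call of TYMS was lost in 11 of the settings tried. The unfolded protein and ATF4 list (smallest adjusted p = 0.0836, serum in GFP cells), the actin dynamics and nuclear transport list (0.143, serum in G13R cells) and the replication-dependent histones (0.164, difference of responses) passed in no contrast as deposited. Under quantile normalization the actin dynamics list passed for serum in G13R cells (adjusted p = 0.00686) and the unfolded protein list for G13R against GFP cells in normal growth (0.0412). Of 25 actin dynamics genes, 5 rose and 5 fell in GFP cells after serum (5 and 6 adjusted over the list alone), and 6 rose and 1 fell in G13R cells (6 and 2). The monomer-binding genes TMSB4X and GSN rose in GFP (1.92 ± 0.15 and 2.50 ± 0.17) and in G13R cells (1.47 ± 0.15 and 1.86 ± 0.17), while the formin gene FMN2 fell in GFP cells (-1.11 ± 0.28), a call lost without GFP normal replicate 1 and without GFP serum replicate 2 (adjusted p up to 0.11). Of the marker sets, 6 of 8 osteoblast and 5 of 8 epithelial markers could be tested, with maxima of 45.6 FPKM for COL1A1 and 580 for KRT18. Called among them were 1 osteoblast marker, ALPL, and 2 epithelial markers, KRT8 and KRT18, which are named after their values were seen. After serum ALPL rose in G13R cells (0.70, adjusted p = 0.0181), KRT8 in GFP cells (0.32, adjusted p = 0.0495) and KRT18 in GFP and G13R cells (0.46 and 0.44, adjusted p = 0.00533 and 0.0154). KRT18 was lower in G13R than in GFP cells after serum (-0.53, adjusted p = 0.0449). In the same order these 5 calls were lost in 5, 10, 1, 5 and 10 of the settings tried, with adjusted p up to 0.111, 0.292, 0.0565, 0.116 and 0.349. Among these settings were leaving out any G13R library for ALPL, GFP normal replicate 1 for KRT18 in GFP cells, every G13R library but normal replicate 2 for KRT18 in G13R cells, and any single library but GFP serum replicate 1 for KRT8 and for KRT18 between the cells. The leukocyte, neural and endothelial sets had 0 tested genes and maxima of 0.815 FPKM for PTPRC, in GFP serum replicate 2, 1.26 for GFAP and 0.499 for VWF.

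HSPA1A, HSPA1B and HSPA6 were higher in G13R cells in both conditions. The values argued against reads of HSPA1A or HSPA1B as the source of the HSPA6 signal, since HSPA6 relative to the sum of the others was at least 1.91 times higher in G13R than in GFP libraries in normal growth and 2.41 times after serum, and HSPA6 and HSPA1A share 0% of 50-base windows. HSPA6 and HSPA1B windows were not compared. HSPA7 shares 56.28% of its windows with HSPA6, so the values of HSPA6 and HSPA7 are not fully separate. HSPA7 had a log2 fold change in G13R cells of 1.31 ± 0.20 in normal growth (limma adjusted p = 0.0622) and 1.25 ± 0.20 after serum (limma adjusted p = 0.0397). Library scaling would need a fold near 0, and the smallest HSPA1A log2 fold change over both scalings and conditions was 1.59. A rise of heat shock genes in general cannot be told apart from a narrower one, because the other 12 list members had a median of -0.125 in normal growth with 4 above 0, and 0.243 after serum with 11 above 0. An effect of the mutant, which the design names, stays open and was not tested apart from other differences between the cells. Added actin expression is among these differences, since no group expressed an added unmutated actin.

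After serum, camera at the preset correlation placed the starvation and sterol lists higher and the ribosome biogenesis list lower in both kinds of cell, while with an estimated correlation none passed (adjusted p = 0.405 to 0.5). In GFP and G13R cells, 12 and 6 of 18 starvation genes rose and 1 fell in each, 24 of 25 sterol genes rose in each, and 22 and 10 of 22 ribosome biogenesis genes fell. Withdrawal of serum before it was added could leave such a state, and the starvation list median was 0.364 in G13R (0.217 under quantile normalization) and 0.975 in GFP cells after serum. The labels name no serum-starved group, so withdrawal and stimulation cannot be told apart here.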
